A study of Mus musculus with 6 samples.

How the data were processed

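RNA of 6 mouse samples was hybridised to Affymetrix arrays, 1 sample for each of 2 lines at days 0, 4 and 7. Samples were grouped by their titles, which name the DNMT1 form and the day. For the deletion line at day 0, the source label describes differentiated cells while the title gives day 0 and the same label describes stem cells for the other line, so the title was used. The RNA carried biotin and was labelled with the standard Affymetrix protocol, per the labels' protocols.

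The deposited values are signals that the authors made with MAS5, per the submitters' processing notes, and they were read here as log2 from the values themselves. The MAS5 version, the scaling target, the log base and the handling of the lowest values are not given in the sources used here. The base was read from the values: they ran from 0 to 15.68, and the trimmed mean of 2 to their power, with 2% left out at each end, was between 496.7 and 496.9 on all 6 arrays, as after global scaling of linear MAS5 signals. Array medians lay between 6.02 and 6.19, and 350 to 514 of 45037 probe sets per array were listed at 0. No detection calls were used here. Global scaling makes levels relative to the mean of each array, so a shift of most genes in 1 direction would be removed.

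Values were raised to the power of 2, values below a floor were set to it, and log2 was taken again. The floor was the median over the arrays of each array's 40th percentile, a signal of 41.2 (log2 5.37). It is a percentile and not a measured background. Probe sets were named by the platform annotation, dated 2016, and symbols were checked through gene identifiers against a RefSeq table: 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none, 34741 of those with 1 symbol were found in the table, and 0 symbols changed. Probe sets with several symbols or none named no gene. A gene took the value of its probe set with the highest mean signal and was measured where that mean was at or above the floor, which held for 13277 of 18193 genes. Of these, 7856 had more than 1 probe set.

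Differences were fitted in R 4.3.3 with limma 3.58.1, with line and day as additive factors over the 6 arrays, moderated variances with a trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The model leaves 2 residual degrees of freedom, to which the variance prior added 5.63. It gave the line difference, day 4 over day 0 and day 7 over day 4. Nothing in the labels says that samples came from repeated cultures. The p-values therefore set a mean difference against the spread between these arrays, which holds the difference of the lines' time courses and technical noise together.

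Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists with at least 5 measured genes, and again with an estimated correlation and with fry. No list call in any comparison held with an estimated correlation or with fry. That loss does not show that correlation between genes made the calls. The formative and definitive endoderm lists had estimated correlations of -0.024 and -0.047, below the preset value, and lost their calls too. With 2 residual degrees of freedom these alternatives may have had little power, which was not tested. Counts adjusted over the list alone used the same gene p-values. The lists covered general, naive and formative pluripotency, primitive streak, definitive and extraembryonic endoderm, mesoderm, blood, neuroectoderm, trophoblast, germline, two-cell stage, imprinted, DNA methylation, p53, interferon, cell cycle, epithelial and mesenchymal, Activin and Nodal, fibroblast, hypoxia, HOX and ribosomal genes. Of 473 list entries 363 were measured. Some genes stand in several lists.

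Comparisons of 1 array with 1 array had no test. They counted genes at least 2-fold apart with the brighter array at least 2 times the floor, and gave a list's median as its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these arrays only. A list's median difference or change is the median over its genes of each gene's difference. It can depart from the difference between median levels.

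Named genes followed a rule. It takes Dnmt1, Dnmt3a and Dnmt3b. For each modelled effect it takes the 10 highest and 10 lowest genes by the smallest difference over the pairs, among genes at least 2-fold apart in the same direction in every pair, called genes before uncalled and unnamed gene models left out. For each list described it takes up to 4 genes with the largest effect. For the line difference at each day and for the difference of the lines' day 7 over day 0 changes, it takes the 5 highest and 5 lowest genes with the brighter array at least 4 times the floor. Pou5f1, the day 7 levels of Ldha and Elf5, Lefty1, Lefty2 and Peg3 were named outside the rule, after their values were seen, as were genes that make up a count of 3 or fewer. The grouping, the tests, the lists, the rule and the alternatives were fixed before the data were examined.

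The fit was tested on simulated arrays of the 13277 genes with 200 genes changed. For the line difference it called 36%, 92%, 98% and 100% of genes changed by 1, 2, 3 and 4 on the log2 scale, with 17 false calls of 180. For day 4 over day 0 it called 22%, 78%, 98% and 100%, with 7 false of 156. For day 7 over day 4 it called 8%, 74%, 96% and 100%, with 6 false of 145. The false share for the line difference, 17 of 180, lay above the adjusted p threshold used for calls. All these shares describe the simulated arrays and need not hold for the real ones. On the real arrays 0 genes were called between the lines, although Nupr1 and Cpt1a had log2 differences of 2.37 and 2.32.

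Alternatives changed the floor, the normalization, the filter on dim genes, the choice of probe set, the variance prior, the other factor, the threshold, the fold and the set test, and left out each array in turn. Plots were drawn with matplotlib 3.10.9.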

Results

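Gene expression was measured on 6 arrays, 1 for each of 2 mouse embryonic stem cell lines at days 0, 4 and 7. Both lines lack their own Dnmt1, Dnmt3a and Dnmt3b genes, which encode the DNA methyltransferases, and both carry a DNMT1 that is expressed throughout. The full-length line carries the complete protein, and the deletion line carries DNMT1 without its N-terminal 602 amino acids. Day 0 cells were stem cells kept in 10% serum with leukaemia inhibitory factor (LIF). Day 4 cells had spent 1 day as embryoid bodies and 3 days attached to the plate without LIF. Day 7 cells had spent 3 further days in 10% KSR medium with 10 ng/ml Activin A, a ligand of the Nodal pathway that the submitters used to bring on primitive streak formation.

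Levels are log2 MAS5 signals, and 13277 of 18193 genes had a mean signal at or above the floor of 5.37 and were tested. Each array held between 13081 and 13448 genes at or above that floor. With 1 array per line and day there were no replicates. An adjusted p from limma set a mean time change, or a mean line difference, against a residual spread moderated over genes. That spread came from how far the 2 lines differed in a time change, or how far a line difference varied between days. The number of arrays limited the precision. Where a level lay at the floor, a difference from it is a lower bound, written as at least that size. Each DNMT1 form was present in 1 line, so form and line cannot be told apart.

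The first principal component held 43.2% of the variance and placed the day 0 arrays at -32.1 in the full-length line and -45.4 in the deletion line. The full-length arrays of days 4 and 7 lay at 39.6 and 38.4. In the deletion line the day 4 array lay at 16.2 and the day 7 array at -16.6. The second component, with 23.6%, placed the deletion line's day 7 array at 46.8, the full-length day 7 array at 17.7 and the day 0 arrays at -13.2 and -17.2. Across genes, which are not independent replicates, the lines correlated at 0.974 at day 0, 0.974 at day 4 and 0.951 at day 7. The day 7 array of the deletion line correlated at 0.958 with the full-length day 0 array, at 0.951 with the full-length day 7 array, and at 0.953 and 0.956 with its own line's day 0 and day 4 arrays.

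The genes altered in these cells were read first. Dnmt1 had levels of 9.65, 8.77 and 8.91 in the full-length line at days 0, 4 and 7 and of 8.97, 8.37 and 8.94 in the deletion line, and the line difference was not called (log2 -0.35, SE 0.22, adjusted p = 0.552). A dimmer Dnmt1 probe set read 7.30, 5.53 and 6.83 in the full-length line and 2.48, 3.32 and 6.82 in the deletion line. Dnmt3a was not measured, since its 5 probe sets had mean signals below the floor. Dnmt3b had levels between 8.21 and 9.71 over the 6 arrays, with no call in any comparison. Where these probe sets lie relative to the deleted parts of the genes and to the expressed DNMT1 was not examined, so their levels check nothing about the labels.

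The change from day 0 to day 4 addresses how cells of both lines responded to leaving LIF and growing as embryoid bodies and then attached. Of the measured genes, 6 of 16 of the formative and primed epiblast and 3 of 21 of extraembryonic endoderm rose, while 5 of 16 of naive pluripotency and 7 of 18 of fibroblasts fell. Fgf5, a growth factor of the primed epiblast, rose at least 46.4-fold at its brightest probe set (log2 5.54, SE 0.38, adjusted p = 0.0018). Its levels there went from 5.52 to 11.70 in the full-length line and from the floor to 10.26 in the deletion line. Another Fgf5 probe set had a log2 change of 3.75. Klf4, a transcription factor of naive pluripotency, fell 12.4-fold (log2 -3.63, SE 0.18, adjusted p = 0.00074). Pou5f1, which encodes the pluripotency factor OCT4, stayed between 13.21 and 14.02 on all 6 arrays and was not called.

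In all, 210 genes were called between days 4 and 0, 117 higher and 93 lower, and 2157 genes had an unadjusted p under 0.05. Both lines showed at least a 2-fold change in the same direction for 405 higher and 228 lower genes, called or not. With arrays scaled to equal medians, the split of calls turned to 102 higher and 124 lower, and the median over all genes shifted by -0.12. Leaving out either line's day 0 or day 4 array left 1 array for that day. The loss of all calls in these fits therefore does not show that they depend on any 1 array. Of the 210 genes, 0 changed sign in them. Without the full-length or the deletion line's day 7 array, 100 and 129 genes were called, of which 85 and 98 were among the 210. Calls also numbered 0 without the filter on dim genes, 14 with probe sets averaged, 16 without a variance trend, 2 without a variance prior and 18 without the line in the model.

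Among the genes that rose in both lines were Slc39a8, a zinc and manganese transporter (log2 5.09, with another probe set at 2.76), and Car4, a carbonic anhydrase (log2 4.46). The keratins Krt8 and Krt18 rose 13.9-fold and 9.68-fold, Cnn1, a smooth muscle calponin, by log2 3.54, and Slc35d3 and Chst15 by at least log2 3.43 and 3.92, with another Chst15 probe set at 1.29. The genes that fell included the lysozyme genes Lyz1, from 10.20 and 12.76 to the floor in both lines, and Lyz2, with a log2 change of -4.70 that is a lower bound in size. The immediate-early genes Fos and Fosb fell from 13.41 and 9.28 in the full-length line, and from 13.57 and 9.69 in the deletion line, with Fos at 9.14 and 8.85 at day 4 and Fosb at the floor. Mgp and Tnc, which encode matrix proteins, and the myosin gene Myo1f also fell, with log2 changes of -3.21, -3.83 and -3.41 that are lower bounds in size.

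The naive pluripotency list was called lower at day 4 (16 genes, median log2 -1.44, camera adjusted p = 1.5e-12, and adjusted p = 0.49 with an estimated correlation). Of its 16 genes 5 fell, 11 were not called and 13 were called lower adjusted over the list alone. Beside Klf4, Tcl1 fell by 2.46, while the log2 changes of Jam2 (-2.40) and Tbx3 (-2.04) missed the threshold. Its median change was -2.07 in the full-length line and -0.93 in the deletion line, a difference between lines that was not tested. The general pluripotency list was also called lower, with a median of -0.50 and 0 of 18 genes called (adjusted p = 0.0070, and adjusted p = 0.67 with an estimated correlation).

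The formative and primed epiblast list was called higher (16 genes, median log2 0.49, adjusted p = 0.023, and adjusted p = 0.49 with an estimated correlation). In it 6 genes rose and 10 were not called, and adjusted over the list alone 6 were called higher and 1 lower. Beside Fgf5, these included the kinase gene Pim2 (log2 2.65), the zinc finger gene Sall2 (log2 2.42) and Pou3f1, which encodes the POU factor OCT6 (log2 2.03). The list's median change was 1.08 in the full-length line and 0.40 in the deletion line.

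The extraembryonic endoderm list was called higher (21 genes, median log2 0.82, adjusted p = 2.7e-05, and adjusted p = 0.49 with an estimated correlation). Ttr, Afp and Dab2 rose and 18 genes were not called, and adjusted over the list alone 9 were called higher. The serum protein gene Ttr went from the floor to 8.69 and 9.45, and Afp, which encodes alpha-fetoprotein, from the floor to 8.84 and 8.81. Sox17, a transcription factor gene held by this list and by the definitive endoderm list, had a log2 difference of 2.08 (adjusted p = 0.073). The definitive endoderm list was called higher with a median of 0.82 and 2 of 13 genes called, Foxa1 (log2 2.13) and Cldn6 (log2 2.06), and 5 called higher adjusted over the list alone (adjusted p = 0.0065, and adjusted p = 0.49 with an estimated correlation).

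The trophoblast list was called higher (14 genes, median log2 1.07, adjusted p = 0.0060, and adjusted p = 0.67 with an estimated correlation), with Krt8 and Krt18 as its 2 called members, which are keratins of simple epithelia in general. Adjusted over the list alone, 2 were called higher and 1 lower. The blood and endothelium list was called higher with 2 of 15 genes called, the embryonic globin genes Hbb-bh1 and Hba-x (at least log2 2.76 and 2.27), and 5 called higher adjusted over the list alone (adjusted p = 0.0060, and adjusted p = 0.49 with an estimated correlation). The mesoderm and cardiac list was called higher with 1 of 13 genes called, the cardiac actin gene Actc1 (at least log2 3.51), and 4 called higher adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.49 with an estimated correlation).

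The fibroblast list was called lower (18 genes, median log2 -2.02, adjusted p = 1.1e-10, and adjusted p = 0.49 with an estimated correlation), with 7 genes called lower and 11 not called. Adjusted over the list alone, 12 were called lower and 2 higher. Bgn, which encodes the matrix proteoglycan biglycan, fell 11.8-fold, S100a4 15.7-fold, and the matrix gene Postn with a log2 change of -3.91, a lower bound in size. The log2 difference of the collagen gene Col3a1, -3.91 and also a lower bound, was not called (adjusted p = 0.066), and another probe set gave -1.20. Levels of this list also differed between the lines at day 0, where the median over its genes of the line difference was 1.20, higher in the deletion line.

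The cell cycle list was called lower with a median of -0.18 and 0 of 19 genes called (adjusted p = 0.023, and adjusted p = 0.49 with an estimated correlation), and the germline list with a median of -0.20 and 0 of 27 genes called (adjusted p = 0.027, and adjusted p = 0.74 with an estimated correlation). Without the full-length day 0 array the germline median turned to 0.13. The other 12 lists were not called, with adjusted p from 0.056 to 0.90. Single called genes in them were Amot in the primitive streak and mesendoderm list (log2 2.90, and 0.42 at the lowest of its 3 probe sets), Pmaip1 in the p53 list (log2 1.16) and Inhbb, which encodes an activin subunit, in the Activin and Nodal list (log2 -3.07, a lower bound in size, and -0.82 for its other probe set). In the neuroectoderm list 2 genes were called lower, Stmn2 and Ncam1, whose 3 probe sets ranged from -2.26 to 0.

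**Figure D1:**
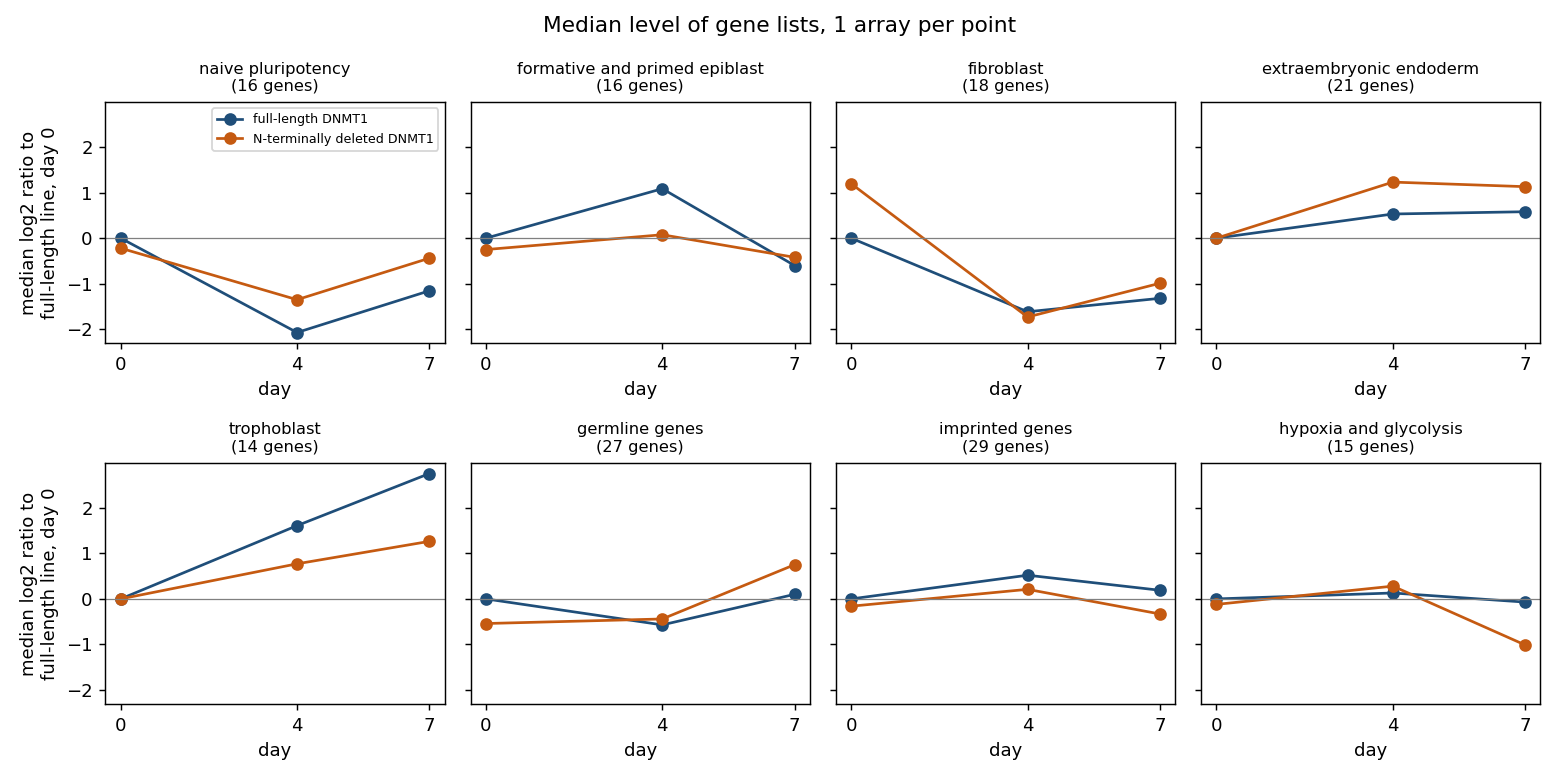
Each panel plots, for 1 gene list, the median over its measured genes of the log2 ratio to the full-length line at day 0 (vertical axis) against the day (horizontal axis), with 1 array per point and no error bar because there were no replicates. The naive pluripotency medians were lowest at day 4 in both lines, and the trophoblast list's day 7 median lay 2.75 above day 0 in the full-length line.

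The change from day 4 to day 7 covers 3 days in KSR medium with Activin A, so time, medium and Activin A go together. Lgals3, which encodes the lectin galectin-3, rose 6.06-fold (log2 2.60, SE 0.19, adjusted p = 0.017), from 10.18 to 12.95 in the full-length line and from 10.61 to 13.04 in the deletion line. Mylpf, a myosin light chain gene, rose 4.56-fold (log2 2.19, SE 0.20, adjusted p = 0.048). These were the 2 called genes, and 0 fell. Germline and naive pluripotency lists were called higher and the formative and primed epiblast list lower, each lost when the correlation was estimated (adjusted p = 0.64, 0.64 and adjusted p = 0.53 with an estimated correlation).

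With limma, 1582 genes had an unadjusted p under 0.05 and 53 an adjusted p under 0.1. At least 2-fold changes in the same direction in both lines were seen for 186 higher and 113 lower genes. Both calls were lost when any of the 6 arrays was left out, and between 0 and 3 genes were called over the other settings at the same threshold. This comparison and the preceding one share the day 4 arrays, so a chance value at day 4 moves them in opposite directions, and the medians of day 7 against day 0 are given beside the list results.

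Further genes at least 2-fold higher at day 7 in both lines were not called. They included Stra8, a gene of meiotic entry, with levels of 6.36 and 6.04 at day 4 and of 9.42 and 9.37 at day 7 (adjusted p = 0.075). Khdc3, Nlrp4f and Crxos, genes of oocytes and early embryos, had log2 differences of 2.44, 3.12 and 3.06, Mt4 and Tex19.2 of 3.16 and 2.96, and Krt14 of at least 2.35. Crxos lay at 8.58 and 8.57 at days 0 and 7 in the full-length line, and at 8.11 and 9.89 in the deletion line. Among genes at least 2-fold lower in both lines, also not called, Fgf5 had a log2 difference of -2.48 and the thyrotropin-releasing hormone gene Trh of -2.85 (adjusted p = 0.090 for both). Slc35d3, Kctd12b and Irs4 had log2 differences of -2.90, -2.21 and -2.10, with another Irs4 probe set at -0.12. Those of Mal2, Has2 and Col27a1, -2.27, -2.33 and -2.00, are lower bounds in size.

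The germline list was called higher at day 7 (27 genes, median log2 0.82, adjusted p = 9.8e-09, and adjusted p = 0.64 with an estimated correlation). It holds genes of germ cells that DNA methylation silences in other cells. Of its genes 0 were called over all genes and 9 were called higher adjusted over the list alone. Dazl, which encodes a germ cell RNA-binding protein, lay at 10.07 and 13.53 at days 4 and 7 in the deletion line (adjusted p = 0.23 over both lines). Magea5 and Smc1b had log2 differences of 2.99 and 2.27. Against day 0, the median change of the list's genes at day 7 was 0.10 in the full-length line and 1.27 in the deletion line.

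The naive pluripotency list was called higher (median log2 0.84, adjusted p = 1.9e-06, and adjusted p = 0.64 with an estimated correlation), with 0 of 16 genes called over all genes and 9 called higher adjusted over the list alone. Dppa3, Tbx3, Tcl1 and Klf4 had log2 differences of 1.60, 1.58, 1.49 and 1.46, with another Klf4 probe set at 0.76. Its day 7 median was -1.16 against day 0 in the full-length line and -0.26 in the deletion line. The formative and primed epiblast list was called lower (median log2 -0.94, adjusted p = 1.6e-08, and adjusted p = 0.53 with an estimated correlation), with 0 of 16 called over all genes and 9 called lower adjusted over the list alone. Pim2, Pou3f1 and Sall2 had log2 differences of -2.60, -2.31 and -1.48. Against day 0, the formative list's day 7 median was -0.60 in the full-length line and -0.24 in the deletion line.

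The trophoblast list was called higher (median log2 0.80, adjusted p = 0.00035, and adjusted p = 0.64 with an estimated correlation), with 0 of 14 genes called and 2 called higher adjusted over the list alone. Its homeobox members Rhox6 and Rhox9 had log2 differences of 1.53 and 1.54, and the trophoblast factor gene Elf5 lay at 8.22 in the full-length line at day 7 and at or near the floor elsewhere. The hypoxia and glycolysis list was called lower (15 genes, median log2 -0.67, adjusted p = 0.00011, and adjusted p = 0.64 with an estimated correlation), with 0 called over all genes and 6 called lower adjusted over the list alone. Its median was -0.12 in the full-length line and -1.41 in the deletion line, and against day 0 it was -0.07 and -0.72. The trophoblast medians against day 0 were 2.75 and 0.83.

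The imprinted list was called lower (29 genes, median log2 -0.24, adjusted p = 0.0053, and adjusted p = 0.64 with an estimated correlation), with 0 called over all genes and 6 lower and 1 higher adjusted over the list alone. Grb10 and Mirg had log2 differences of -2.09 (-0.83 for another probe set) and -1.75, and Cdkn1c, a cell cycle inhibitor gene, of 2.56. The blood and endothelium list (median -0.68, adjusted p = 0.034) and the Activin and Nodal list (median -0.42, adjusted p = 0.047) were called lower, each with 0 genes called and 1 called lower adjusted over the list alone, and adjusted p = 0.64 with an estimated correlation for both. Id1 and Eomes of the Activin and Nodal list had log2 differences of -1.13 and -0.92, and without the full-length day 7 array the list's median was -0.09. In the full-length and deletion lines, medians of day 7 against day 0 were 0.19 and -0.23 for the imprinted list, 0.22 and 0.03 for the blood and endothelium list and -1.16 and -0.07 for the Activin and Nodal list. The primitive streak and mesendoderm list was not called (10 genes, median -0.42, adjusted p = 0.24). Its genes T, Mixl1, Gsc, Tbx6 and Lhx1, among others, were not measured, so the list does not cover them. The list's median change was -1.17 in the full-length line and 0.07 in the deletion line, a difference that was not tested. The remaining lists had adjusted p from 0.065 to 0.98.

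**Figure D2:**
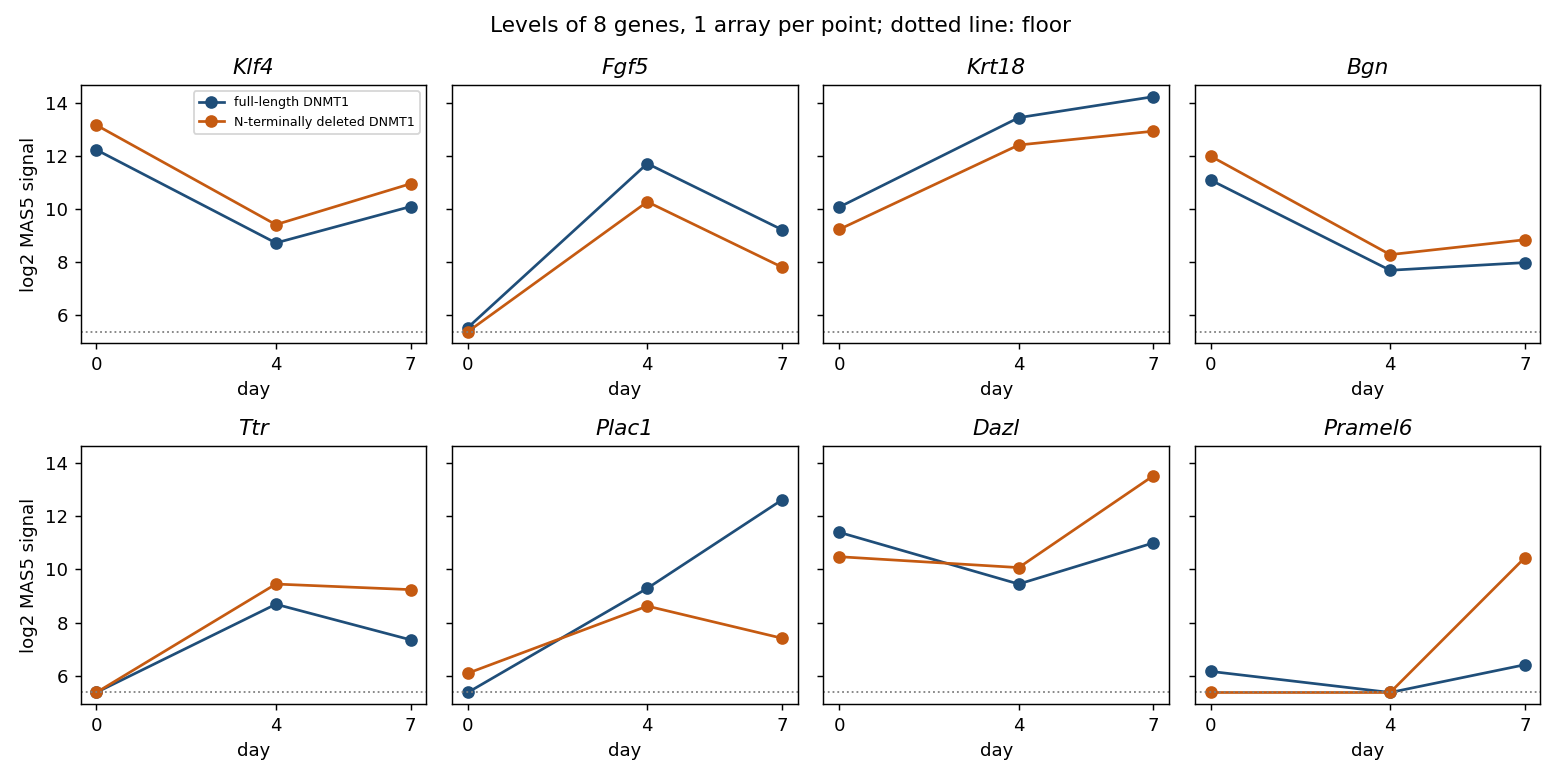
Each panel plots the log2 MAS5 signal (vertical axis) of 1 gene against the day (horizontal axis) in the full-length and deletion lines, with 1 array per point, no error bar because there were no replicates, and a dotted line at the floor of 5.37. Plac1 lay at 12.62 in the full-length line at day 7 and at 7.41 in the deletion line. Klf4, plotted from its brightest probe set, was lowest at day 4 in both lines.

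The comparison of the lines asks how cells with the deleted DNMT1 differed from cells with the full protein. Over all 3 days, 0 genes were called by limma between the lines, with 1624 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0712, for Malat1. That nuclear RNA was 3.12-fold higher in the deletion line (log2 1.64, SE 0.15), at 12.25, 11.94 and 12.44 in the full-length line and at 13.59, 13.86 and 14.10 in the deletion line. Its 7 probe sets above the floor ranged from -0.30 to 1.68, and with probe sets averaged its log2 difference was 0.59. The same test on probe sets called 2.

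At least a 2-fold difference in the same direction at all 3 days was seen for 10 genes higher and 13 lower in the deletion line, none of them called. Those higher included Nupr1, a stress-response gene (log2 2.37), Cpt1a, which encodes a carnitine palmitoyltransferase of fatty acid oxidation (log2 2.32), Mavs, an adaptor of RNA sensing (log2 1.37), Spink1, Snhg3, Ninl, Zfp141 and Rb1cc1. The 2 probe sets of Rb1cc1 differed in sign, at -0.54 and 1.27. Over its 3 probe sets Cpt1a ranged from 0.44 to 2.32, and one nearly as bright read 9.68, 9.03 and 9.35 in the full-length line and 9.33, 9.69 and 10.35 in the deletion line, so the 2-fold difference at all 3 days rests on 1 probe set. It does so too for Mavs, whose other probe set had a log2 difference of 0.87. Lower in the deletion line were Cysrt1, Ankrd2 and Dnah11, with log2 differences of -1.88, -1.53 and -1.40 that are lower bounds in size, Pgap4 (-1.66), the planar polarity gene Prickle1 (-1.38), Farp1 (-1.37), the ligand gene Wnt4 (-1.36), Lpcat4 (-1.36), Aif1l (-1.22) and Pex2 (-1.13). Other probe sets of Wnt4, Aif1l and Pex2 had log2 differences as small as -0.32, -0.49 and -0.33, so their 2-fold differences at all 3 days also rest on 1 probe set.

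Between the lines 6 lists were called, each with 0 genes called over all genes. Higher in the deletion line were the extraembryonic endoderm list (median log2 0.49, adjusted p = 2.6e-05), the naive pluripotency list (median 0.59, adjusted p = 7.2e-05) and the fibroblast list (median 0.40, adjusted p = 0.020), each with adjusted p = 0.78 with an estimated correlation. Adjusted over the list alone, 0, 1 (Klf4) and 2 (Bgn and S100a4) genes were called. The fibroblast list rested on day 0: without either line's day 0 array its median was 0.0050 and its adjusted p was 0.94. At days 0, 4 and 7 the medians were 0, 0.76 and 0.44 for extraembryonic endoderm and -0.22, 0.76 and 0.84 for naive pluripotency, so neither list was higher at day 0. Afp, Ttr and Cubn of the extraembryonic endoderm list had log2 differences of 0.90, 0.88 and 0.88, with Afp and Ttr at the floor in both lines at day 0, and Nr5a2 of the naive list of 0.91.

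Lower in the deletion line were the imprinted list (median log2 -0.40, adjusted p = 0.00019, and adjusted p = 0.78 with an estimated correlation), the trophoblast list (median -0.98, adjusted p = 0.038, and adjusted p = 0.78 with an estimated correlation) and the hypoxia and glycolysis list (median -0.42, adjusted p = 0.038, and adjusted p = 0.79 with an estimated correlation). At days 0, 4 and 7 the medians were -0.16, -0.37 and -0.82 for the imprinted list, 0, -0.39 and -1.51 for the trophoblast list and -0.12, -0.01 and -1.05 for the hypoxia and glycolysis list, so day 7 had the lowest median in each. Of 29 imprinted genes 15 were lower and 0 higher at all 3 days, and Peg3 was called adjusted over the list alone (log2 -0.99). Nnat and Sgce had log2 differences of -1.73 and -1.24. In the trophoblast list Krt8 and Krt18 were called lower adjusted over the list alone (log2 -1.02 and -1.06). The other 17 lists had adjusted p from 0.057 to 0.98.

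Single days compare 1 array with 1 array and have no test. At day 0, 791 genes were at least 2-fold apart, 417 higher and 374 lower in the deletion line. The split turned to 368 higher and 438 lower with quantile normalization, and was 509 and 331 with arrays scaled to equal medians. Higher at day 0 were Ptn, which encodes the growth factor pleiotrophin (7.66 and 10.60 in the full-length and deletion lines, with another probe set at 6.86 and 7.10), Ifi202b (at the floor and 8.12), Lyz1 (10.20 and 12.76), Ptx3 (5.90 and 8.44) and Tmem176b (5.84 and 8.26). Lower were Dnah8 (8.10 and 5.52), the immunoproteasome gene Psmb8 (7.78 and the floor), Meiob (8.01 and 5.80) and Cpn1 (7.52 and the floor). The probe sets of the actin-binding protein gene Gsn disagreed, with the brightest at 10.16 and 7.14 and others at 9.76 and 10.03, 8.86 and 10.06, 9.17 and 9.40, and 6.25 and 5.52, so no direction is given. The fibroblast list's median difference of 1.20 lay at percentile 100 of 10000 matched random lists, and 11 of its 18 genes were at least 2-fold higher in the deletion line. The germline list's median of -0.54 lay at percentile 0.

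At day 4, 790 genes were at least 2-fold apart, 322 higher and 468 lower in the deletion line. Higher were Lgals2 (6.09 and 9.03 in the full-length and deletion lines, with another probe set at 6.33 and 7.16), Cpt1a (7.28 and 9.98), the receptor gene Pdgfra (5.66 and 8.05), the proteoglycan gene Srgn (9.62 and 11.97) and Dcdc2a (5.52 and 7.81, with another probe set at 6.55 and 6.39). The Cpt1a probe set nearly as bright read 9.03 and 9.69. Lower were Fgf8, a growth factor gene of the primitive streak (9.43 and the floor), Efemp1 (9.60 and 5.56), Gbp2, an interferon-induced GTPase gene (10.29 and 7.51), Actc1 (10.53 and 7.76) and Trim67 (8.51 and 5.80). The medians of the naive pluripotency and extraembryonic endoderm lists, both 0.76, lay at percentile 100 of matched random lists. Those of the primitive streak and mesendoderm list (-0.99), the Activin and Nodal list (-0.545), the formative and primed epiblast list (-0.47) and the imprinted list (-0.37) lay at percentile 0.

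At day 7, 1708 genes were at least 2-fold apart, 524 higher and 1184 lower in the deletion line, and with arrays scaled to equal medians 653 were higher and 929 lower. Higher were Lox, which encodes a collagen cross-linking enzyme (5.45 and 9.48 in the full-length and deletion lines), Pramel6 (6.41 and 10.44), the keratin gene Krt17 (5.55 and 9.06), Nupr1 (7.25 and 10.26) and Cpt1a (8.02 and 11.01, with the probe set nearly as bright at 9.35 and 10.35). Lower were Plac1, a placental gene (12.62 and 7.41), Ptn (10.30 and the floor, with another probe set at 6.35 and 6.26), Fndc3c1 (10.99 and 6.65), Ldoc1 (11.07 and 7.19) and Six6 (9.07 and the floor).

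Day 7 medians of the trophoblast (-1.51), hypoxia and glycolysis (-1.05) and imprinted lists (-0.82) lay at percentile 0 of matched random lists. In these lists 9 of 14, 9 of 15 and 10 of 29 genes were at least 2-fold lower in the deletion line, and 0 were 2-fold higher. The medians of the naive pluripotency (0.84), germline (0.73) and general pluripotency (0.56) lists lay at percentile 100, with 7 of 16, 12 of 27 and 4 of 18 genes at least 2-fold higher. Ldha, which encodes lactate dehydrogenase, lay at 14.34 in the full-length line and at 12.28 in the deletion line.

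**Figure D3:**
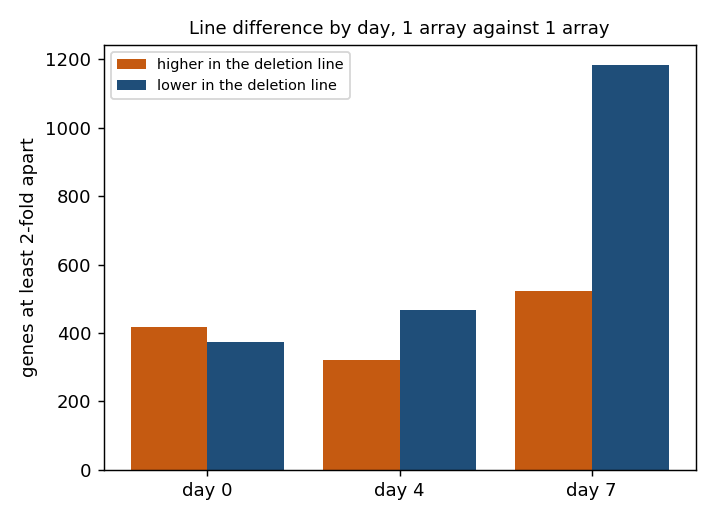
Bars give the number of genes at least 2-fold higher and at least 2-fold lower in the deletion line than in the full-length line (vertical axis) at each day (horizontal axis), from 1 array against 1 array, with no error bar because there were no replicates. The day 7 bars, 524 and 1184, are the tallest in each direction.

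The change from day 0 to day 7 also differed between the lines, a difference with no residual degree of freedom and so no test. As deletion minus full-length line, it was at least log2 4.82 for Pramel6 and 3.54 for Gkn2, 3.82 for Msc, 3.73 for the meiotic cohesin gene Smc1b and 3.59 for the nucleic acid sensor gene Zbp1. It was -4.22 for the connexin gene Gjb5. For Ptn (-7.87), Plac1 (-5.93), Eif4e3 (-4.51) and the neural factor gene Sox1 (-4.18) the values are lower bounds in size. All of these come from the brightest probe set, and other probe sets of Pramel6, Zbp1, Ptn, Eif4e3 and Sox1 gave smaller differences. The second Ptn probe set given above differed little between the lines at days 0 and 7. Over the 3 Ptn probe sets above the floor, the line difference over all days ranged from -1.06 to 0.18, so its value here holds for the brightest only. Taken gene by gene, the lines' difference in the day 0 to day 7 change had a median of 1.24 over the germline list and of -1.42 over the trophoblast list. These medians are not the gaps between the lines' median changes given above.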

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

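The tests for fewer differentiated cells at day 7, for day 0-like cells and for array scaling of the fibroblast list were chosen after the result was seen.

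Effects of opposite sign, between the lines for a time change or between days for the line difference, were searched among the lists, where both medians had to lie in the outer tails of matched random lists, and among the genes named in the text, not among all genes. A line difference can change sign while both lines move the same way. With 1 array per line and day none of these differences was tested. From day 4 to day 7 the median change over the genes of the p53 and cell death list was 0.35 in the deletion line and -0.30 in the full-length line. The median over a list's genes of the line difference at day 7 against day 0 was 0.565 and -0.335 for general pluripotency, 0.73 and -0.54 for germline, and 0.27 and -0.305 for p53 and cell death. At day 7 against day 4 it was 0.315 and -0.47 for the formative and primed epiblast list, 0.27 and -0.35 for p53 and cell death, and 0.37 and -0.545 for Activin and Nodal. Median levels at day 7 were instead lower in the deletion line than in the full-length line for these lists. They were 8.78 and 9.565 for formative, 10.425 and 10.435 for p53, and 9.75 and 9.985 for Activin and Nodal. Of the 16 formative genes, 1 was at least 2-fold higher and 6 at least 2-fold lower in the deletion line at day 7, against the sign of the median difference of 0.315.

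Of the genes named in the text, those that changed at least 2-fold from day 0 to day 4 in opposite directions in the deletion and full-length lines were Cpn1 (1.05 and -2.15), Efemp1 (-3.49 and 2.44), Ptn (-3.03 and 1.09) and Tmem176b (-2.36 and 1.52). From day 4 to day 7 they were Col3a1 (2.59 and -1), Efemp1 (1.78 and -3.47), Fgf8 (1.00 and -2.55), Gbp2 (2.09 and -1.13), Ldoc1 (-1.40 and 1.48), Lefty1 (2.13 and -1.45), Lefty2 (1.85 and -1.31), Pdgfra (-1.16 and 1.48), Plac1 (-1.21 and 3.33), Ptn (-2.20 and 1.55) and Zbp1 (2.49 and -1.09).

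Among the same named genes the line difference, at least 2-fold on each day, changed direction between day 7 and day 0 for Eif4e3 (-3.01 and 1.49), Gjb5 (-2.60 and 1.62), Jam2 (1.15 and -1.19), Lefty1 (1.66 and -1.23), Msc (2.62 and -1.20), Ptn (-4.93 and 2.94), Smc1b (1.59 and -2.14), Tmem176b (-1.72 and 2.42) and Zbp1 (1.63 and -1.96). Between day 7 and day 4 it did so for Col3a1 (2.44 and -1.15), Efemp1 (1.21 and -4.04), Lefty1 (1.66 and -1.92), Lefty2 (1.90 and -1.26) and Zbp1 (1.63 and -1.95).

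For these named genes the line difference changed direction between day 4 and day 0 for Col3a1 (-1.15 and 2.41), Cpn1 (1.05 and -2.15), Efemp1 (-4.04 and 1.89), Eif4e3 (-1.03 and 1.49), Ptn (-1.18 and 2.94) and Tmem176b (-1.46 and 2.42). Values of Col3a1, Cpn1, Eif4e3, Fgf8, Ptn and Zbp1 that involve a level at the floor are lower bounds in size. All of these values come from the brightest probe set, and for Eif4e3, Col3a1, Pdgfra and Ptn another probe set showed no opposite signs in at least 1 of these comparisons. Separately, among 10092 probe sets without a single gene name, which the comparisons leave out, 209 were at least 2-fold higher and 127 at least 2-fold lower in the deletion line at day 7, also untested.

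Fibroblast-list genes were lower at day 4 than at day 0 in both lines. Scaling differences are argued against, since the list's median change after quantile normalization was -2.11. Feeder cells or other fibroblasts in the day 0 samples are a candidate explanation. Of the 10 members at least 2-fold lower at day 4 in both lines, 100% were higher in the deletion line at day 0. A larger share of such cells there would give that direction. The median difference was 1.23, but the differences ran from 0.13 for Thy1 to 2.41 for Col3a1, so the members shared a direction and not a size. The brightest of the 10 at day 0 were Bgn (11.08 and 11.98 in the full-length and deletion lines) and Col1a2 (10.39 and 11.73). The labels name no feeder cells, and a loss of these transcripts by the stem cells themselves stays open and was not tested.

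More genes differed between the lines at day 7 than at days 0 and 4. Noise of single probe sets is argued against, since day 7 differences of 2 probe sets of a gene correlated at r = 0.743. That r was taken over 3848 genes and was 0.35 at day 0 and 0.552 at day 4. Both probe sets were read on the same arrays, so r cannot argue against a fault of 1 array or sample. Line differences also spread wider at day 7 (SD 0.69) than at day 0 (SD 0.51), which by itself raises r. Fewer differentiated cells in the deletion line's day 7 sample may contribute: genes called lower at day 4 had a median line difference 1.10 above that of genes called higher (0.37 and -0.73). The same medians were 0.37 and -0.33 at day 0 and 0.24 and -0.39 at day 4, so part of this gap was present earlier. An effect of the deleted DNMT1 stays open and untested, since form and line go together.

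Germline-list genes had a higher median at day 7 than at day 4, with 0 of 27 genes called over all genes. The list's camera call was lost with an estimated correlation (adjusted p = 0.64) and with fry (adjusted p = 0.50). For the deletion line, a return of day 0-like cells is argued against as the whole cause, since the genes' median change from day 0 to day 7 was 1.27. At day 7, 14 of 27 genes lay at least 2-fold above day 0. Array scaling is argued against by a median change from day 4 of 1.19 after quantile normalization. For the full-length line, with a median of 0.10 against day 0 and 4 of 27 genes at least 2-fold above it, day 0-like cells cannot be told apart from a rise within cells, since its genes went both ways. By these medians naive genes did not come back by a like share. Median changes to day 4, from day 4 to day 7 and from day 0 to day 7 were -0.57, 0.33 and 0.10 for germline genes. They were -2.07, 0.81 and -1.16 for naive genes. With 1 array per day the difference in share was not tested, so it decides no cause. Loss of DNA methylation stays open and was not tested, since methylation was not analysed here.

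Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. With day in the model all 10 called at least as many genes as the real one, which called 0, and the highest of the others called 0. At an unadjusted p under 0.05 the real split gave 1624 genes, and splits that part only the day 7 arrays gave 1552. For genes at least 2-fold apart in the same direction at all 3 days, 1 of 4 ways of assigning each day's arrays to the lines gave as many as the real 23, also too few for a share under 0.05, and the highest other gave 20.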

How the results depend on the processing

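All alternatives here were chosen before the data were examined, and no test in this part was chosen after the result was seen. No paired analysis was possible because the labels pair no samples beyond line and day. Where a count moved the cause was not tested, except that fewer arrays, a wider threshold and a larger fold change counts by construction. Without 1 array, that array's group has no sample left, and the spread is pooled over the others.

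Genes called between the lines numbered 0, or 2 with one test per probe set, 1 at an adjusted p under 0.1, and 0 to 0 with 1 array left out. For day 4 over day 0 the 210 calls became 127 with the floor at the 60th percentile, 0 without a filter on dim genes, 114 with the filter at 4 times the floor, 14 with probe sets averaged, 16 without a variance trend, 2 without a variance prior, 18 without the other factor, 548 at an adjusted p under 0.1, and 0 to 129 with 1 array left out. Without the full-length or deletion line's day 0 or day 4 array 0 remained, and without the full-length and deletion line's day 7 arrays 85 and 98 of the 210 remained. Shared with the 210 were 145 without a floor, 146 with the floor added to every signal, 16 without a trend, 1 without a prior and 18 without the other factor.

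For day 7 over day 4 the 2 calls became 1 with the floor at the 60th percentile, no floor, the floor added, quantile normalization, the filter at 4 times the floor, one test per probe set or without the other factor. They became 0 with probe sets averaged, without a trend or without a prior, 53 at an adjusted p under 0.1, and 0 to 0 with 1 array left out. Called lists became 0 with an estimated correlation and 0 with fry in each of the 3 comparisons. The 6 between the lines became 3 with the floor at the 20th percentile and 7 to 10 with 1 array left out, the 11 of day 4 over day 0 became 7 without a filter and 8 to 12, and the 8 of day 7 over day 4 became 6 to 9.

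Genes at least 2-fold apart became, at 3-fold, with the floor at the 20th and at the 60th percentile, 112, 2110 and 336 for the lines at day 0, 177, 2054 and 350 at day 4, and 531, 3086 and 1019 at day 7. For day 4 over day 0 they became 641, 3164 and 1006 in the full-length line and 467, 2725 and 712 in the deletion line, and for day 7 over day 4 they became 283, 2343 and 592, and 442, 2828 and 784. With probe sets averaged, 475 and 515 differed between the lines at days 0 and 4. With equal medians the deletion line's day 4 over day 0 split went from 828 higher and 540 lower to 681 and 674.

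The tested direction of 3 lists reversed with 1 array left out, where medians ran from 0.0050 to 0.80 for the fibroblast list between the lines, from -0.70 to 0.13 for the germline list in day 4 over day 0, and from -0.80 to -0.0863 for the Activin and Nodal list in day 7 over day 4. The values 0.0050, 0.13 and -0.0863, with adjusted p of 0.94, 0.94 and 0.72, came without either line's day 0 array, the full-length day 0 array and the full-length day 7 array. Over the named genes, 734 values kept direction and either kept their side of the threshold or, in comparisons without a test, stayed within a set margin. Of the rest, 223 kept direction and were no longer called, 46 untested values moved beyond that margin, and 0 reversed. Levels near the floor limit the low end: genes there give lower bounds.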

Other observations

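The genes Lefty1 and Lefty2 were chosen after the result was seen, and no test in this part was. These Nodal targets had levels of 13.84, 13.33 and 11.88 (Lefty1) and 12.45, 12.03 and 10.72 (Lefty2) in the full-length line at days 0, 4 and 7, and of 12.61, 11.41 and 13.54, and 11.63, 10.77 and 12.62, in the deletion line. Neither was called in any comparison.

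The epithelial and mesenchymal list was not called for day 4 over day 0 (adjusted p = 0.29), with Krt8, Krt18 and the claudin gene Cldn7 (log2 1.98) higher and the repressor gene Zeb1 (log2 -2.12, and 0.10 for a dimmer probe set) lower among its genes. The two-cell stage list, with 5 measured genes, was not called (adjusted p = 0.61, 0.41 and 0.79 for day 4 over day 0, day 7 over day 4 and the lines). The median line difference of its genes at day 7 was 2.29. There Pramel6 lay at 10.44 and Pramel7 at 8.86 in the deletion line, against 6.41 and 6.45 in the full-length line.

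In the same order of comparisons, adjusted p was 0.82, 0.32 and 0.31 for the interferon list, 0.18, 0.15 and 0.40 for HOX genes, 0.90, 0.88 and 0.076 for ribosomal proteins, 0.18, 0.83 and 0.27 for the DNA methylation list, and 0.18, 0.88 and 0.057 for neuroectoderm. It was 0.90, 0.98 and 0.61 for the p53 and cell death list. Ribosomal protein genes had a median line difference of -0.50 at day 0 and of -0.06 at day 7.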
